A study of Arabidopsis thaliana with 12 samples.

How the data were processed

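Gene expression was measured in 12 samples of above-ground parts of Arabidopsis thaliana, 5 of the wild type and 7 of the double mutant, on Affymetrix GeneChip arrays. The values were used as deposited: the authors made log2 signals per probe set with RMA from the affy package, whose versions the labels do not give. RMA corrects background, normalizes quantiles and summarises probes, yet the distributions were not exactly equal between arrays. The table held 22810 probe sets, and 64 Affymetrix controls were left out, which left 22746. Of these 13513 were assigned to 1 gene, 503 to several and 8730 to none, and only those with 1 gene were named. The assigned genes were matched by gene number to the RefSeq annotation of TAIR10.1, which covered 13436, and 23 mitochondrial probe sets were matched by symbol. Probe sets named MSH1 or RECA3 were not found in the annotation, so these genes were not analysed here. The design text and the treatment protocol give different heat lengths, 2 h and about 24 h, and neither could be preferred.

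Samples were grouped by genotype and treatment. A limma model with a mean per group was fitted to all 12 samples, so that the untreated wild type with its 2 samples borrowed its spread from all groups. The fit had 8 residual degrees of freedom, 3.22 prior degrees of freedom, a prior SD of 0.145 and a median residual SD of 0.159 on the log2 scale. The 5 comparisons were heat in each genotype, the genotypes without and after heat, and the difference of the heat responses. Tests were moderated by empirical Bayes and two-sided, and p was adjusted over all probe sets by Benjamini-Hochberg at 0.05. Replicate numbers were taken not to pair samples across groups, since residuals of same-numbered samples had correlations of -0.348 to 0.265, with 3 of 15 above 0.1. Errors of differences are the moderated SE of limma, and errors of group means are SD.

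Genes were also tested as 22 lists. These lists, the comparisons, the rule for naming genes and most alternatives were chosen before the data were examined. Another 15 lists were drawn up later from gene names alone, and they were adjusted separately. Each list used the probe set with the highest mean per gene. The 7 fixed lists with at least 5 measured genes and the 15 later ones were tested with limma's camera, which compares a list with all other genes, with the correlation between genes estimated per list. Smaller lists are given as counts of called genes. Most held few of their listed genes under a name: 1 of 17 for defence, 1 of 18 for the clock, 1 of 11 for jasmonate and 1 of 10 for senescence. For photosynthesis 3 of 30 were named, for flavonoids 3 of 19 and for antioxidant enzymes 4 of 24. Their counts therefore do not speak for whole pathways. No gene of the lists for heat shock factors, DNA damage response and flower markers was measured under its own name. The list of the mitochondrial genome and that of its copy on chromosome 2 shared 11 probe sets.

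Genes named in the text follow a rule. Per comparison it took the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, a condition not used for the difference of responses. It added up to 2 rises and 2 falls per list, or else the member with the smallest p, and the target genes where named. Brief functions come from general knowledge of the genes, since the annotation gave no products.

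Alternatives were centring on the 3 measured reference genes, keeping the upper 0.5 of probe sets by mean, a replicate block, leaving out each sample, trend and robust moderation, array weights, a size of at least 1 on the log2 scale and a fit of only the compared groups. The size and the fit of only the compared groups were run for counts and not for single genes. For lists they were camera with a preset correlation of 0.01, fry, the mean of all probe sets of a gene and an adjustment with the later lists. The alternatives for list tests were run for the fixed lists, while the later lists were tested again only with the preset correlation and fry. Quantile normalization between arrays and the joint adjustment were chosen after the data were seen. The procedure was tested on simulated data with known differences and unmoved lists. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.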

Results

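Transcript levels were measured on Affymetrix arrays in the shoots of Arabidopsis thaliana, in the Col-0 wild type and in an msh1 recA3 double mutant of the same background. MSH1 and RECA3 are nuclear genes for proteins that keep organelle DNA intact. The 12 arrays fell into 4 groups: untreated wild type (n = 2), heated wild type (n = 3), untreated double mutant (n = 4) and heated double mutant (n = 3). Plants were 8 weeks old, grown at 24 °C and heated at 37 °C. The design text gives 2 h of heat and the treatment protocol about 24 h, so the length of the heat is open. The values were log2 RMA signals of 22746 probe sets, of which 13513 were assigned to a single gene and could be named. No probe set carried the name MSH1 or RECA3 in the annotation, so the target genes were not analysed here. The number of arrays limits the precision, above all in the untreated wild type.

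Heated and untreated samples separated on the first principal component, which held 71.1% of the variance. The second held 10.2% and set the genotypes apart. On it, heated double mutant replicate 3 scored 8.73, nearer to the heated wild type (13.5 to 16.3) than to the other heated double mutants (-22.5 and -26.8). Untreated double mutant replicates 1 and 2 scored -2.95 and -0.964, and replicates 3 and 4 scored -22.9 and -30.9.

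**Figure D1:**
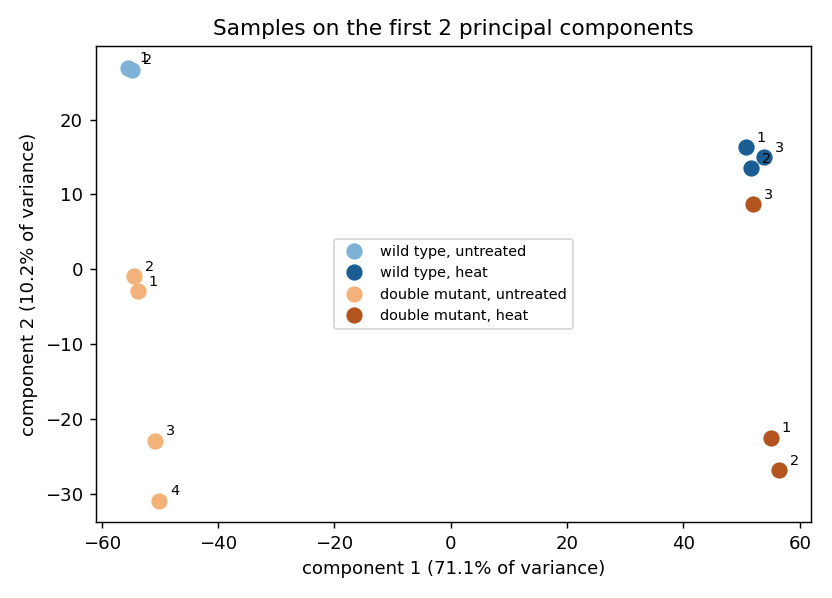
Samples on principal components 1 and 2 of the log2 RMA values, in units of the component scores, each point an array and its digit the replicate number. Heated arrays lie at the right, and heated double mutant replicate 3 scored 8.73 on component 2.

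Heat in the wild type (3 heated against 2 untreated arrays) asked which transcripts respond to heat in normal plants. Heat raised all 8 measured small heat shock proteins, which bind unfolding proteins, by 4.01 to 9.46 on the log2 scale (8 adjusted over the list alone). HSP22.0 (AT4G10250) went from 3.80 ± 0.09 (SD, n = 2) to 12.94 ± 0.09 (SD, n = 3), and HSP17.6C-CI (AT1G53540) rose by 9.46 ± 0.26 (SE). All 6 measured large chaperones and co-chaperones rose (6 adjusted over the list alone), among them the peptidyl-prolyl isomerase ROF2 by 8.66 ± 0.36 (SE) and the Hsp70-Hsp90 organising protein HOP3 by 7.46 ± 0.28 (SE). Of 4 measured genes of the ER unfolded protein response 3 rose (4 adjusted over the list alone), with the transcription factor BZIP28 up by 2.26 ± 0.14 (SE). Untreated HSP22.0 (3.80), HSP23.5 (3.90) and HOP3 (3.99) lay near the lower quartile of the arrays, which ran from 3.67 to 3.79, so the sizes of their rises rest on signals that were not shown to exceed background.

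Transcripts of the mitochondrial genome rose together in the heated wild type. Of 28 measured mitochondrial genes 27 passed the test (27 adjusted over the list alone), with a median log2 difference of 3.32, and the complex I subunits nad6 and nad5 rose by 5.88 ± 0.31 and 5.11 ± 0.21 (SE). In the copy of mitochondrial DNA inserted in chromosome 2 of the nucleus, 31 of 46 measured genes rose (33 adjusted over the list alone), with a median of 2.27. The median was 1.05 over the 35 probe sets of the insertion alone and 3.44 over the 11 shared with mitochondrial genes. These lists shared 11 probe sets that match both copies, so they are not independent. Probe sets were sorted by their listed genes and not by sequence, so those of the insertion alone may also read mitochondrial transcripts. Of 10 measured genes of mitochondrial dysfunction and alternative respiration 5 rose (5 adjusted over the list alone), including the mitochondrial chaperone HSP23.5 by 7.96 ± 0.19 (SE), also on the small heat shock protein list, and the stress marker UPOX by 3.49 ± 0.18 (SE). Among nuclear genes of oxidative phosphorylation 2 of 7 rose (3 rose and 1 fell adjusted over the list alone), led by cytochrome c CYTC-2 at 2.32 ± 0.09 (SE), but 1 rose and 1 fell after quantile normalization between arrays. Of 76 plastid genes 7 rose and 1 fell (4 and 1 adjusted over the list alone), with psbT up by 1.73 ± 0.24 (SE), but with the same normalization 4 rose and 5 fell.

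Several groups tied to growth and metabolism held members that fell in the heated wild type. Among cell wall genes, the endoglucanase GH9C2 fell by 3.59 ± 0.24 (SE) and the expansins EXPA4 and EXPA8, which loosen walls, changed by -3.10 ± 0.18 and -2.70 ± 0.24 (SE). Of 18 expansins 6 fell and 1 rose (8 and 1 adjusted over the list alone). All 3 measured genes of flavonoid and anthocyanin synthesis fell (3 adjusted over the list alone), and DFR, dihydroflavonol reductase, changed by -2.66 ± 0.33 (SE). Of 8 genes of branched-chain amino acid breakdown 6 fell (6 adjusted over the list alone), among them IVD at -1.41 ± 0.19 (SE). The clock gene GI rose by 2.21 ± 0.28 (SE), and 1 of 4 cold, drought and abscisic acid genes rose, the dehydrin COR47 by 1.98 ± 0.35 (SE). In the smaller groups 1 of 4 antioxidant enzymes fell, 1 of 3 photosynthesis genes rose (1 fell and none rose after quantile normalization), the single defence and senescence genes measured, WRKY53 and SAG29, fell by 1.84 ± 0.53 and 1.57 ± 0.45 (SE), and no jasmonate, root marker or organelle DNA maintenance gene passed (1 root marker lower adjusted over the list alone).

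By limma, 6027 of 22746 probe sets differed in the heated wild type at an adjusted p under 0.05, 3112 higher and 2915 lower, and 2228 of them by at least 1 on the log2 scale. The balance turned after quantile normalization between arrays, with 2790 higher and 3449 lower. Of the 7 gene lists large enough for a set test, 5 shifted upward with an estimated correlation: the mitochondrial genome (adjusted p = 0.000238), the small heat shock proteins, the large chaperones and the chromosome 2 insertion (each adjusted p = 0.00128) and mitochondrial dysfunction (adjusted p = 0.00858). The largest named rise of the mitochondrial dysfunction list was that of HSP23.5, which is also on the small heat shock protein list. The dysfunction list was not tested without this gene, so its shift is not independent of that list. Oxidative phosphorylation (adjusted p = 0.223) and the plastid genome (adjusted p = 0.546) did not pass, nor did expansins (adjusted p = 0.387) or branched-chain amino acid breakdown (adjusted p = 0.329). The mitochondrial dysfunction call ended when arrays were centred on the reference genes (adjusted p = 0.0524, the highest of its 19 camera alternatives, the lowest being 0.000211 with the preset correlation), and the count fell to 3912 without untreated wild type replicate 1. The calls of UF3GT, GR2, SDH2-1, WRKY53, SAG29, PUB19, TIP41L and SAND were also lost in at least 1 alternative, while 39 of 47 named calls held in every alternative run for single genes. These were 18 for 38 of them and 17 for AT3G28550, too dim for the upper 0.5 of probe sets, and included neither the size of at least 1 nor the fit of only the compared groups.

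Heat in the double mutant (3 heated against 4 untreated arrays) asked the same of the plants labelled msh1 recA3. All 8 small heat shock proteins rose by 3.48 to 9.18 on the log2 scale (8 adjusted over the list alone), and HSP22.0 went from 3.80 ± 0.06 (SD, n = 4), again near the lower quartile, to 12.89 ± 0.07 (SD, n = 3). All 6 large chaperones and co-chaperones rose (6 adjusted over the list alone), with ROF2 up by 8.07 ± 0.30 (SE) and HOP3 by 7.53 ± 0.23 (SE), as did all 4 unfolded protein response genes (4 adjusted over the list alone), with BZIP28 at 2.28 ± 0.12 (SE). Mitochondrial transcripts rose in 27 of 28 genes (27 adjusted over the list alone), with a median of 2.94, and nad6 rose by 6.17 ± 0.26 (SE). In the chromosome 2 insertion 39 of 46 genes rose (39 adjusted over the list alone), with a median of 2.32. The median was 1.93 over the 35 probe sets of the insertion alone and 3.37 over the 11 shared with mitochondrial genes.

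Genes of mitochondrial dysfunction went both ways in the heated double mutant: 3 of 10 rose and 2 fell (4 and 2 adjusted over the list alone, 6 and 2 with arrays centred on the reference genes). HSP23.5 rose by 7.06 ± 0.16 (SE) and UPOX by 1.26 ± 0.15 (SE), whereas the alternative NAD(P)H dehydrogenases NDB4 and NDB3 fell by 1.51 ± 0.15 and 1.32 ± 0.19 (SE). Of 7 oxidative phosphorylation genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, 3 and 1 with arrays centred on the reference genes), with CYTC-2 at 1.88 ± 0.07 (SE) and the cytochrome c oxidase subunit COX5B-1 at -0.83 ± 0.17 (SE). The median of this list was -0.05, while its mean was 0.14 and its set test pointed upward. Of 76 plastid genes 1 rose and 18 fell (0 and 15 adjusted over the list alone), with ndhA at -1.16 ± 0.21 (SE), but 11 rose and 10 fell once arrays were centred on the reference genes.

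The largest named fall in the heated double mutant was that of DFR, at -4.70 ± 0.28 (SE), and all 3 flavonoid genes fell (3 adjusted over the list alone). Among wall genes EXPA8 changed by -3.98 ± 0.20 (SE), EXPA4 by -3.45 ± 0.15 (SE) and GH9C2 by -3.86 ± 0.20 (SE). Of 18 expansins 8 fell and 2 rose (8 and 2 adjusted over the list alone), and 7 fell and 6 rose once arrays were centred on the reference genes. Branched-chain amino acid genes fell in 7 of 8 cases (7 adjusted over the list alone), with MCCA at -1.09 ± 0.10 (SE). GI rose by 2.49 ± 0.24 (SE), 2 of 4 cold, drought and abscisic acid genes rose, COR47 by 2.54 ± 0.29 and COR15B by 1.78 ± 0.42 (SE), 2 of 4 antioxidant enzymes fell (1 fell and 1 rose with that centring), 1 of 3 photosynthesis genes fell (none with that centring), and the root-associated glucosidase PYK10 fell by 1.73 ± 0.29 (SE). The beta-tubulins TUB7 and TUB9 fell by 1.44 ± 0.16 and 0.92 ± 0.08 (SE).

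By limma, 7725 probe sets differed in the heated double mutant, 3140 higher and 4585 lower, and 2154 of them by at least 1 on the log2 scale. This balance depended on the scale: with arrays centred on the 3 measured reference genes, which moved the median of all probe sets by 0.25, 10412 were higher and 2675 lower. Of these reference genes SAND itself fell by 0.71 ± 0.09 (SE). All counts given for this comparison with arrays centred on these 3 genes therefore carry part of that fall. With an estimated correlation 4 of 7 lists shifted upward, namely the chromosome 2 insertion (adjusted p = 0.00118), the mitochondrial genome (adjusted p = 0.000304) and both chaperone lists (each adjusted p = 0.00131). Mitochondrial dysfunction (adjusted p = 0.166), oxidative phosphorylation (adjusted p = 0.548) and the plastid genome (adjusted p = 0.419) did not pass, though the plastid genome was called lower with the preset correlation (adjusted p = 0.0043, against up to 0.629 in its other camera alternatives) and by fry (adjusted p = 0.0204), which tests against no change and called all 7 lists. Whether responses differed between genotypes was tested separately, and 17 probe sets passed. Named calls held in every alternative run for single genes in 43 of 48 cases, 18 for 41 of them and 17 for UGT75C1 and UGT73C1, the others being SDH1-1, psbB, rpl16, GR1 and LHCB4.1.

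Of the 15 lists added later 1 shifted with heat in each genotype. Chaperones found by symbol rose in 15 of 17 genes in the wild type and 13 of 17 in the double mutant (16 and 15 adjusted over the list alone) and shifted upward (adjusted p = 0.00381 and 0.00814). This list shared 4 genes with the fixed chaperone lists, so its shift is not independent of theirs. Single ER folding and degradation genes rose, 9 and 8 of 13 (1 and 0 fell), with DER1 up by 2.73 ± 0.34 and 3.15 ± 0.28 (SE), but the list did not pass (adjusted p = 0.159 and 0.247). Nor did autophagy (adjusted p = 0.752 and 0.781), where 5 and 4 of 10 genes rose, with ATG8H up by 1.33 ± 0.25 (SE) in the wild type, while 1 and 2 autophagy genes fell. Nuclear photosynthesis genes went up in 4 and down in 1 of 22 in the wild type (2 and 5 after quantile normalization), and up in 2 and down in 10 in the double mutant (3 and 1 with arrays centred on the reference genes).

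Of 14 SWEET sugar transporters 1 rose and 2 fell in the heated wild type and 2 rose and 4 fell in the heated double mutant (8 rose and 3 fell with arrays centred on the reference genes), with SWEET1 up by 2.24 ± 0.31 and 2.49 ± 0.26 (SE). UDP-glycosyltransferases rose in 4 and fell in 4 of 47 in the wild type, and in 6 and 5 in the double mutant (31 and 4 with that centring). Tau glutathione transferases, 11 in all, rose in 1 and fell in 1, then rose in 2 and fell in 3 (7 and 1 with that centring). Of 17 DNA repair genes 2 fell in the wild type and 4 in the double mutant (6 rose and 2 fell with that centring), the polymerase gene POLA3 by -1.28 ± 0.11 and -1.19 ± 0.09 (SE). Among 17 organelle editing factors 2 rose and 1 fell in the wild type, and 4 rose and 2 fell in the double mutant. Of 9 ubiquitin ligases of the PUB family 1 rose and 3 fell, then 2 rose and 1 fell. Among 9 xyloglucan endotransglucosylases 2 fell, then 1 rose and 1 fell. Of 7 tubulins 1 rose and 2 fell, then 3 fell, and of 11 pollen genes 2 rose in each.

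The heat responses of both genotypes ran closely together. Across 22746 probe sets, which are not independent replicates, their log2 differences had a Pearson r of 0.912 and a Spearman rho of 0.778. Of 4628 probe sets called in both, 4623 had the same sign. Both were higher for 2214 (430 expected from the separate counts) and both lower for 2409 (588 expected). HSP17.6C-CI rose by 9.46 in the wild type and 9.18 in the double mutant, nad5 rose by 5.11 and 4.39, and EXPA4 changed by -3.10 and -3.45. Without any 1 of the 12 samples r stayed between 0.884 and 0.918.

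**Figure D2:**
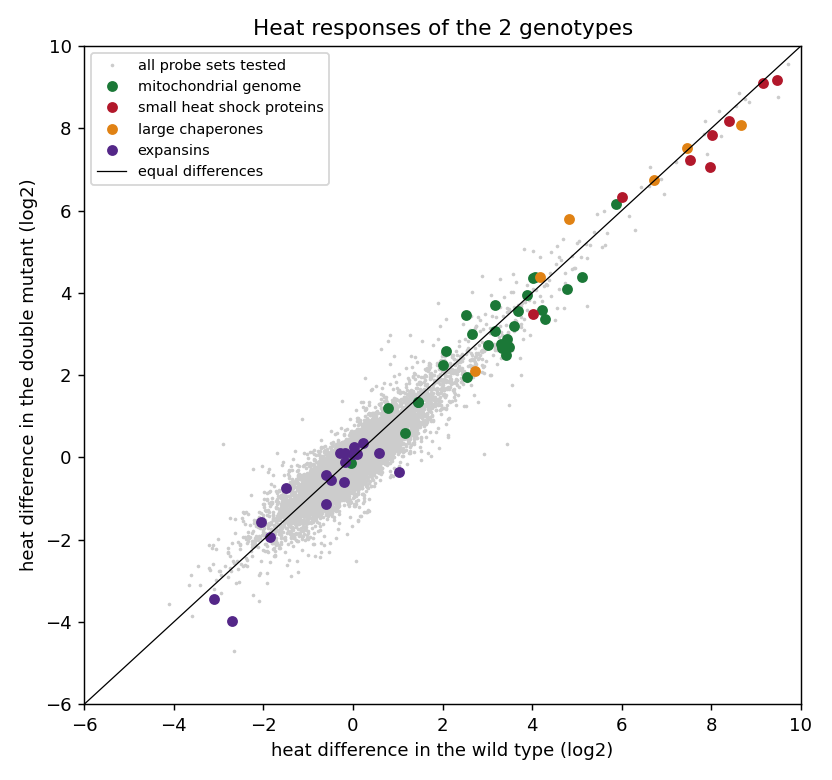
Log2 heat difference in the wild type (x axis) and in the double mutant (y axis), each point a probe set; members of 4 gene lists are coloured and the line marks equal differences. The small heat shock proteins reach 9.46 in the wild type and 9.18 in the double mutant, and 27 of 28 mitochondrial genes rose in each.

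The untreated genotypes (4 double mutant against 2 wild-type arrays) were compared to find which transcripts differ before any heat. Transcripts linked to mitochondrial stress were higher in the double mutant. AT12CYS-2 (AT5G09570), a small cysteine-rich mitochondrial protein, stood at 9.32 ± 0.11 (SD, n = 4) against 4.68 ± 0.13 (SD, n = 2), a log2 difference of 4.65 ± 0.14 (SE). UPOX (AT2G21640) was higher by 2.89 ± 0.17 (SE), and the alternative NAD(P)H dehydrogenases NDB4 (AT2G20800) and NDB3 (AT4G21490) by 2.69 ± 0.17 and 2.57 ± 0.22 (SE). In all, 5 of 10 measured genes of mitochondrial dysfunction were higher (6 adjusted over the list alone) and none lower, the fifth being HSP23.5 at 1.08 ± 0.18 (SE), from a wild-type level of 3.90 near the lower quartile of the arrays (3.67 to 3.79).

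The MATE-type efflux transporters AT2G04050 and AT2G04070 were higher in the untreated double mutant by 4.90 ± 0.23 and 3.03 ± 0.22 (SE), the first from a wild-type level of 3.48, below the lower quartile of the arrays (3.67 to 3.79), and AT2G41730, whose probe set bears the suffix for probes that can match other transcripts, by 4.24 ± 0.22 (SE). Of 28 mitochondrial genes 16 were higher (20 adjusted over the list alone), with a median of 0.89, among them the cytochrome c maturation gene ccb452 at 1.90 ± 0.22 (SE) and cox1 at 1.47 ± 0.19 (SE). That count was 12 with arrays centred on the reference genes and 8 after quantile normalization, and no mitochondrial gene was called lower in either. In the chromosome 2 insertion 13 of 46 genes were higher (18 adjusted over the list alone), against 9 and 6 under these scalings, led by AT2G07722 at 2.59 ± 0.21 (SE), whose probe set bears the suffix for probes shared between transcripts. The 35 probe sets of the insertion alone had a median of only 0.039, against 1.01 for the 11 shared with mitochondrial genes, and 6 and 7 of them made up the 13 calls. Among oxidative phosphorylation genes only CYTC-2 was higher (2 of 7 adjusted over the list alone), at 0.60 ± 0.08 (SE).

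Anthocyanin genes were higher in the untreated double mutant, DFR by 2.09 ± 0.32 (SE) and UGT75C1 (adjusted p = 0.0192), 2 of 3 measured (3 adjusted over the list alone). PYK10 was higher by 1.72 ± 0.33 (SE), 1 of 2 root markers measured, and GR1 by 0.70 ± 0.16 (SE), 1 of 4 antioxidant enzymes and none under either other scaling. Rubisco activase, RCA, was higher by 0.46 ± 0.09 (SE), 1 of 3 photosynthesis genes, and none under either other scaling. The wall protein gene AT3G28550, an extensin-like gene, was lower, at 3.68 ± 0.25 (SD, n = 4) against 6.86 ± 0.54 (SD, n = 2), a difference of -3.18 ± 0.24 (SE), whose size is limited by a mutant level at the lower quartile of the arrays (3.67 to 3.79). AT5G59170 was lower at -1.60 ± 0.16 (SE), the pectin methylesterase PME61 at -1.41 ± 0.30 (SE) and the expansin EXPB1 at -0.90 ± 0.14 (SE), 1 of 2 expansins lower out of 18. Apart from HSP23.5 no small heat shock protein or large chaperone of the lists passed (1 large chaperone lower adjusted over the list alone). The large chaperones had a median of 0.13 and a mean of -0.01, and their set test pointed downward without passing (adjusted p = 0.689). Of 76 plastid genes 2 were higher, atpB and atpE, each by 0.41, and none with arrays centred on the reference genes or after quantile normalization. Of the added lists, PPR596 was the single editing factor called, at 1.06 ± 0.17 (SE), and SWEET2 was lower at -1.09 ± 0.24 (SE) and SWEET11 higher at 0.62 ± 0.14 (SE). The calls of PPR596, SWEET2 and SWEET11 were lost in 2, 9 and 13 alternatives. No gene passed in the lists for the unfolded protein response, cold, drought and abscisic acid, defence, jasmonate, senescence, clock or organelle DNA maintenance. Adjusted over the list alone, 3 of 4 unfolded protein response genes and the jasmonate gene were higher and the senescence gene lower. These lists held 1 to 4 named genes each, so nothing follows about whole pathways.

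**Figure D3:**
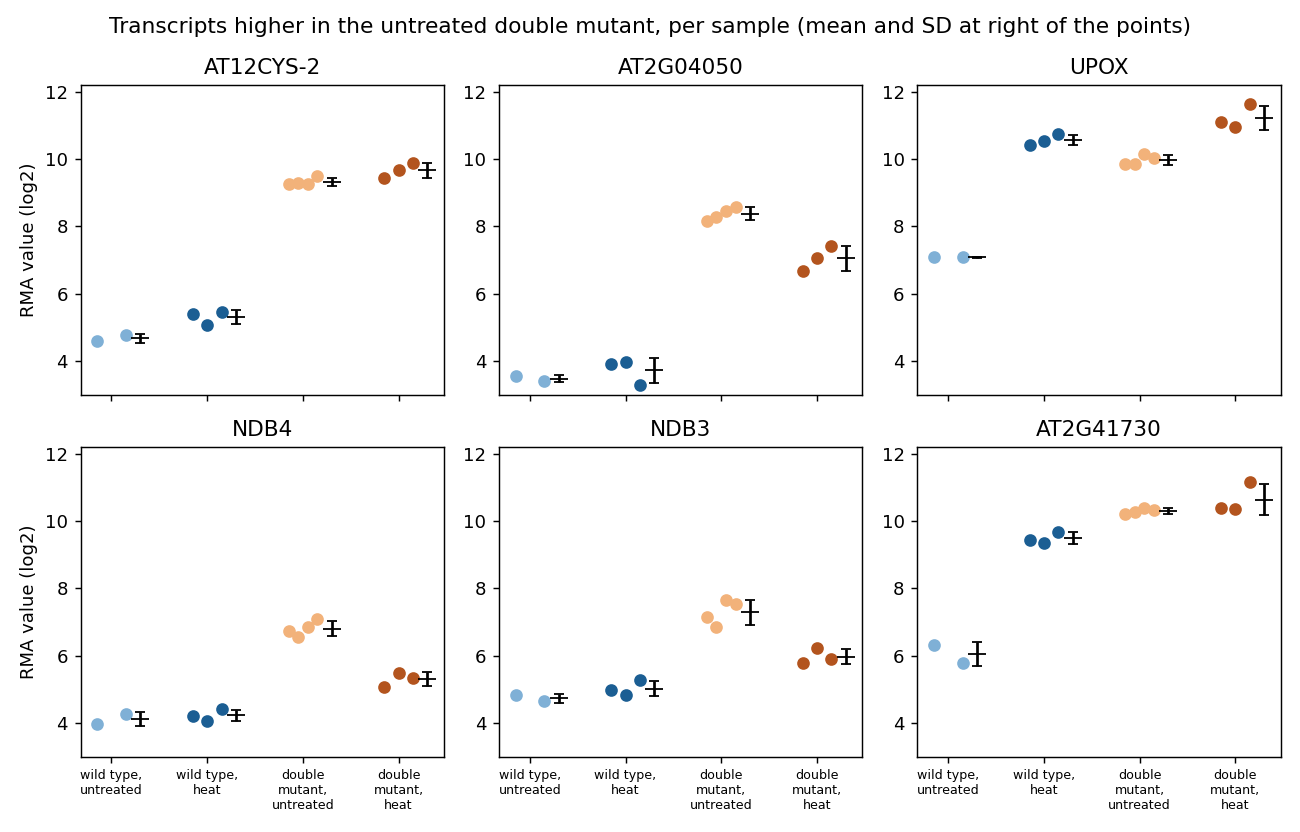
Log2 RMA value of 6 transcripts per sample, with the group mean and SD drawn at the right of each group's points (n = 2, 3, 4 and 3 from left to right). AT12CYS-2 stood at 9.32 in the untreated and 9.66 in the heated double mutant, against 4.68 and 5.30 in the wild type.

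By limma, 613 probe sets differed between the untreated genotypes, 507 higher and 106 lower in the double mutant, 159 of them by at least 1 on the log2 scale. The excess of higher calls depended on the scale: 153 were higher and 580 lower with arrays centred on the reference genes, which moved the median of all probe sets by -0.18, and 165 higher and 110 lower after quantile normalization. The count was 109 with the replicate block and 109 when only these groups were fitted. The block gives untreated double mutant replicate 4, the only sample with that number, its own term. That sample then adds nothing to the comparison, and fewer degrees of freedom are left. The mitochondrial dysfunction and mitochondrial genome lists shifted upward with an estimated correlation (each adjusted p = 0.000888). Oxidative phosphorylation passed narrowly (adjusted p = 0.0432) and lost its call in most alternatives, 13 of 19 with camera, with a range from 0.00735 with the preset correlation to 0.194. The chromosome 2 insertion did not pass (adjusted p = 0.0547, range 3.49e-06 with the preset correlation to 0.172). Fry, which tests against no change, gave adjusted p = 8.15e-07 and 0.000716 for these lists. The count fell to 113 and 140 without untreated wild type replicates 1 and 2, to 271 and 247 without untreated double mutant replicates 3 and 4, and to 381 and 344 without heated wild type replicates 1 and 2. AT2G04050, AT12CYS-2, AT2G41730, AT2G04070, UPOX, NDB4, NDB3, AT2G07722, AT2G32020, AT2G03130, ccb452, AT3G28550 and AT5G59170 kept their calls in every alternative run for single genes, which did not include the fit of only the compared groups, 13 of 32 named, 18 for 11 of them and 17 for AT2G03130 and AT3G28550, and DFR, PYK10, cox1, HSP23.5, CYTC-2 and PME61 were among those that did not.

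After heat (3 double mutant against 3 wild-type arrays) the question was which differences between genotypes were present under stress. AT12CYS-2 stood at 9.66 ± 0.22 (SD, n = 3) in the double mutant and 5.30 ± 0.22 (SD, n = 3) in the wild type, a log2 difference of 4.36 ± 0.14 (SE), and AT2G04050 was higher by 3.32 ± 0.21 (SE), from a wild-type level of 3.73 within the lower quartiles of the arrays (3.67 to 3.79). NDB4 was higher by 1.07 ± 0.16 (SE), so that 2 of 10 mitochondrial dysfunction genes passed (4 adjusted over the list alone). Of 28 mitochondrial genes 7 were higher and none lower (19 adjusted over the list alone), with a median of 0.65, among them the cytochrome c maturation genes ccb452 and ccb382 at 1.24 ± 0.21 and 1.23 ± 0.18 (SE). In the chromosome 2 insertion 14 of 46 genes were higher (28 adjusted over the list alone), with a median of 0.55 (0.41 over the 35 probe sets of the insertion alone and 0.89 over the 11 shared with mitochondrial genes, with 11 and 3 of the calls), led by AT2G07719, also read by a probe set shared between transcripts, at 2.37 ± 0.20 (SE) and AT2G07721 at 2.26 ± 0.29 (SE).

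Tubulin transcripts, which encode the subunits of microtubules, were lower in the heated double mutant. TUB7 differed by -1.01 ± 0.18 (SE) and TUA6 by -0.60 ± 0.10 (SE), 2 of 7 measured (7 adjusted over the list alone), with a median of -0.59. The expansin EXPA8 was lower at -1.08 ± 0.21 (SE), 1 of 18, and the xyloglucan-modifying XTH32 at -1.05 ± 0.19 (SE), 1 of 9. Of 76 plastid genes 5 were lower and none higher (12 adjusted over the list alone), with psbT at -1.19 ± 0.21 and psaJ at -0.94 ± 0.19 (SE). The transcription factor bZIP58 was lower at -1.25 ± 0.19 (SE), and the glycosyltransferase UGT73C1 higher at 1.05 ± 0.16 (SE). None of the 8 small heat shock proteins or 6 large chaperones passed (0 and 0 adjusted over the list alone). The large chaperones had a median of 0.02 and a mean of 0.00, with the set test pointing downward (adjusted p = 0.954). No member passed in the lists for oxidative phosphorylation, unfolded protein response, antioxidants, photosynthesis, clock, cold and drought, defence, jasmonate, flavonoids, senescence, root markers or organelle DNA maintenance. Adjusted over the list alone, 1 unfolded protein response gene and the defence gene were higher. Apart from oxidative phosphorylation these lists held 1 to 4 named genes each, so nothing follows about whole pathways.

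**Figure D4:**
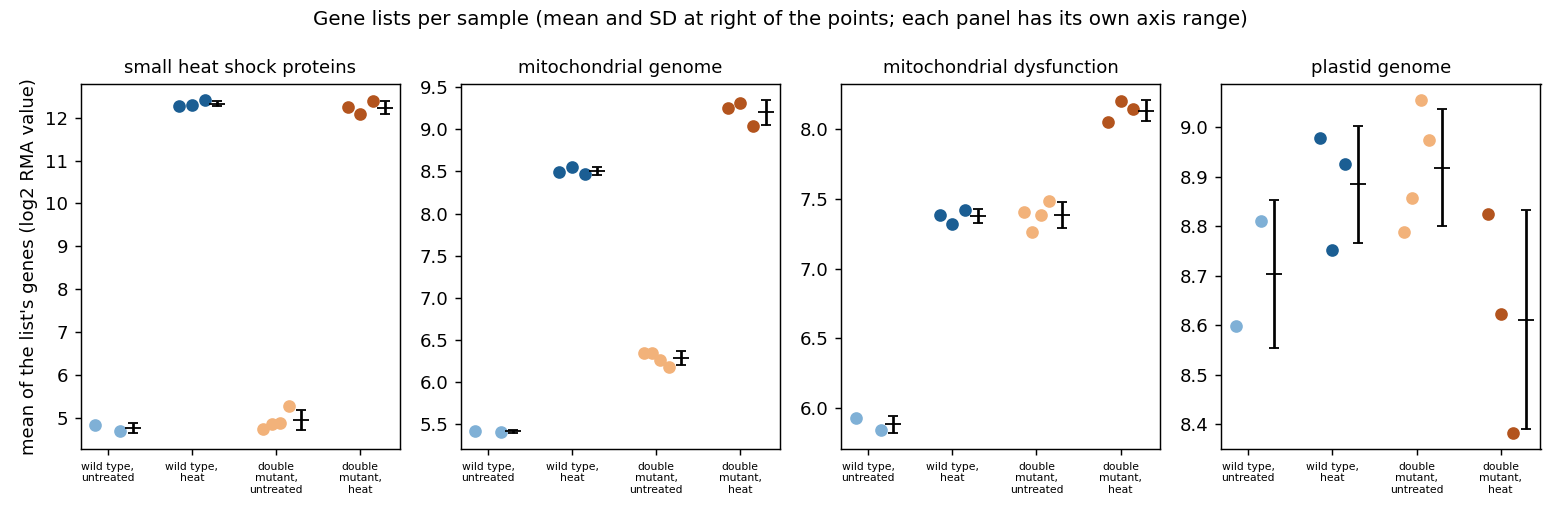
Mean log2 RMA value over the measured genes of 4 lists in each sample, with the group mean and SD at the right of the points; each panel has its own axis range. The mitochondrial genome list averaged 5.42 in the untreated wild type, 6.29 in the untreated double mutant, 8.50 in the heated wild type and 9.20 in the heated double mutant. HSP23.5 belongs to both the small heat shock protein and the mitochondrial dysfunction lists.

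By limma, 204 probe sets differed between the heated genotypes, 113 higher and 91 lower in the double mutant, 88 of them by at least 1 on the log2 scale. Of 7 lists 3 shifted upward with an estimated correlation, namely the mitochondrial genome (adjusted p = 0.000637), the chromosome 2 insertion (adjusted p = 0.00157) and mitochondrial dysfunction (adjusted p = 0.0028), and among 15 lists added later the tubulins shifted downward (adjusted p = 0.0228). The tubulin shift was not tested with samples left out, other scalings or the replicate block. Its called genes TUB7 and TUA6 lost their calls in 5 and 4 alternatives. The plastid genome did not pass (adjusted p = 0.165), except without heated double mutant replicate 1 (adjusted p = 0.0345) and with the preset correlation (adjusted p = 1.84e-08), the highest of its camera alternatives being 0.543. Heated double mutant replicate 3, which lay apart from its group, weighed on this count, which was 1061 without it (513 higher and 548 lower) and 683 with array weights. With the replicate block it was 102, and 33 when only these groups were fitted. The count was 78 and 57 without heated double mutant replicates 1 and 2, and 38, 119 and 110 without heated wild type replicates 1, 2 and 3. AT12CYS-2, AT2G04050, AT2G07719, AT2G07721, ccb382, AT5G02540 and AT3G11600 kept their calls in every alternative run for single genes, again without that fit, 7 of 23 named, 18 for 5 of them and 17 for AT2G07721 and AT5G02540, and the calls of NDB4, ccb452, TUB7, TUA6, EXPA8, XTH32, psbT, psaJ, bZIP58 and UGT73C1 were each lost in at least 1.

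The genotype differences before and after heat were compared in the same way. Across probe sets they had a Pearson r of 0.439 and a Spearman rho of 0.334, and 59 of the 61 probe sets called in both had the same sign. Both were higher for 53 (2.52 expected from the separate counts) and both lower for 6 (0.424 expected). AT12CYS-2, AT2G04050, AT2G04070, NDB4, AT2G32020 and ccb452 were higher in the double mutant in both conditions. Without any 1 of the 12 samples r lay between 0.344 and 0.461.

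Whether heat acted differently in the genotypes was tested as the difference between their heat responses. NDB4 did not pass with heat in the wild type (4.11 ± 0.20, SD, n = 2, against 4.23 ± 0.17, SD, n = 3) and fell in the double mutant (6.81 ± 0.23, SD, n = 4, to 5.30 ± 0.21, SD, n = 3), a difference of responses of -1.62 ± 0.23 (SE). UPOX rose less in the double mutant (-2.23 ± 0.24, SE), and the response of AT2G41730 was also lower there (-3.10 ± 0.30, SE). Both were already higher in the double mutant before heat. AT3G28550 fell with heat in the wild type, from 6.86 to 3.96, and stood at 3.68 and 4.01 in the double mutant, a difference of 3.23 ± 0.33 (SE). The last 3 levels lay near the lower quartile of the arrays (3.67 to 3.79), where a further fall could not be seen, so this difference is not evidence that heat acts differently on the gene. The same limit holds for AT3G61840, at 3.61 to 3.70 in those groups, for AT2G03130, at 3.67 and 3.84 in the wild type, and for NDB4, whose wild-type levels left little room for a fall of the size seen in the double mutant. Of 10 mitochondrial dysfunction genes 2 had a lower response in the double mutant, UPOX by a smaller rise and NDB4 by a fall (4 adjusted over the list alone, 1 over all genes with arrays centred on the reference genes), with a median of -0.40, and NDB4 carries the limit just given. No gene of the mitochondrial or plastid genome passed, although 4 and 2 of them were lower adjusted over the list alone, nor did any of the chromosome 2 insertion, where 5 were higher and 3 lower adjusted over the list alone.

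By limma, 17 probe sets passed for this difference, 5 higher and 12 lower, against 2372 at an unadjusted p under 0.05. Of the 10 that could be named the remainder were AT3G61840 (0.94 ± 0.14, SE), AT2G03130 (-1.58 ± 0.23, SE), AT3G03270 (-1.30 ± 0.15, SE), AT3G51950 (-0.96 ± 0.13, SE), AT3G57880 (-0.85 ± 0.12, SE) and AT5G14520 (-0.79 ± 0.12, SE). With arrays centred on the reference genes, which moved the median of all probe sets by 0.23, 10 were higher and 3 lower, and after quantile normalization 4 and 5. Results with that centring carry part of the heat changes of the reference genes themselves, such as the fall of SAND in the double mutant. The count was 5 with the replicate block, 7 among the upper 0.5 of probe sets and 34 with array weights. The mitochondrial dysfunction list shifted downward (adjusted p = 0.0152 with an estimated correlation) but not with arrays centred on the reference genes (adjusted p = 0.0773) or without untreated wild type replicate 2 (adjusted p = 0.0595), in a range from 1.82e-05 with the preset correlation to 0.0773 over its 19 camera alternatives. No other list passed with an estimated correlation and all samples, the plastid genome having a median of -0.44 (adjusted p = 0.173). The preset correlation called the plastid genome (adjusted p = 3.28e-11) and the chromosome 2 insertion (adjusted p = 0.000502). Fry called the plastid genome (adjusted p = 0.0328) and oxidative phosphorylation (adjusted p = 0.000159), and without heated double mutant replicate 3 the insertion passed (adjusted p = 0.0229). The count was 5 and 1 without untreated wild type replicates 1 and 2, 8, 9 and 7 without untreated double mutant replicates 2, 3 and 4, 6, 5 and 8 without heated wild type replicates 1, 2 and 3, and 6, 3 and 66 without heated double mutant replicates 1, 2 and 3. AT3G28550 alone kept its call in every alternative run for single genes, 17 in its case. The call was lost in 1 alternative for AT2G41730, 2 for UPOX, 4 for AT3G03270, 11 for AT2G03130, 12 for NDB4 and for AT3G61840, 15 for AT3G51950, and 16 for AT3G57880 and for AT5G14520.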

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

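Chosen only after the result was seen were the tests of a mislabelled sample, of mixed RNA, of a gain of all organelle transcripts and of the nuclear copy on chromosome 2, as was quantile normalization, though what it would show was written down before its result.

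A sample far from the others was sought in the untreated double mutant, the only group with 4 samples, as the gap to the nearest sample over the whole range. It exceeded Dixon's critical value for 8 of 101 genes and 0 of 22 list means. Chance alone picks out about 1 in 20 groups. Replicate 4 was high for HSP17.6C-CI (ratio 0.949, 5.21 against 4.19 to 4.24), HSP26.5 (ratio 0.860, 4.29 against 3.26 to 3.40) and AT12CYS-2 (ratio 0.831, 9.49 against 9.25 to 9.29). Replicate 2 was high for HSP22.0 (ratio 0.953, 3.89 against 3.77 to 3.78) and low for psaJ (ratio 0.888, 11.28 against 11.38 to 11.39). Replicate 3 was low for DER1 (ratio 0.904, 4.59 against 5.77 to 5.89), and replicate 1 high for AT3G61840 (ratio 0.916, 3.85 against 3.52 to 3.55) and AT5G02540 (ratio 0.830, 4.65 against 4.05 to 4.15).

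The heat responses of the genotypes differed by a test of the difference itself for 17 probe sets. Of those with names, the response was higher in the double mutant for AT3G28550 (3.23) and AT3G61840 (0.94). It was lower for AT2G41730 (-3.10), UPOX (-2.23), NDB4 (-1.62), AT2G03130 (-1.58), AT3G03270 (-1.30), AT3G51950 (-0.96), AT3G57880 (-0.85) and AT5G14520 (-0.79). The list of mitochondrial dysfunction genes also had a lower response, with a median of -0.40, although 3 of its 10 genes rose and 2 fell in the heated double mutant. That call was lost with arrays centred on the reference genes (adjusted p = 0.0773) and without untreated wild type replicate 2 (adjusted p = 0.0595), in a range of 1.82e-05 to 0.0773 over 19 camera alternatives. The values of AT3G28550, AT3G61840, AT2G03130 and, in the wild type, NDB4 lay in part near the lower quartile of the arrays, where a fall could not be seen, so their differences are not evidence that heat acts differently on them. NDB4 is 1 of the 2 list members that passed, so the list's call shares that limit. The genes AT2G41730, UPOX and NDB4 were already higher in the untreated double mutant, and AT3G28550 already lower.

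Heated double mutant replicate 3 lay near the heated wild type on principal component 2. A wrong label is argued against: over the 613 probe sets called between the untreated genotypes it lay 0.267 from the heated wild type in the double mutant's direction, against -0.03 to 0.04 for the heated wild type and 0.317 and 0.329 for the other double mutants. Mixed wild-type RNA is argued against as well, since it lay 17.43% of the way to the wild type over those probe sets and 84.4% on component 2. Unequal distributions of the RMA values are argued against because the score was still 8.34 after quantile normalization. RMA had itself normalized quantiles before, so unequal intensities of the raw arrays were not tested. Other technical causes, such as a difference in handling, and biological variation between plants remain open and were not tested. The sample may not stand alone: its residuals had correlations of 0.119, 0.388, -0.078 and -0.371 with those of untreated double mutant replicates 1, 2, 3 and 4. Residuals within a group offset each other, so correlations of both signs arise partly by construction. Pairs without this sample reached 0.356 (untreated wild type replicate 2 with untreated double mutant replicate 3) and 0.308 (untreated double mutant replicate 1 with heated wild type replicate 2). Untreated double mutant replicates 1 and 2 also scored higher on component 2 than replicates 3 and 4. A factor shared by these arrays was not tested, since the labels give no batch.

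Higher calls outnumbered lower calls between the untreated genotypes, 507 against 106. With arrays centred on the 3 reference genes the excess reversed, to 153 against 580. A lower range of intensities of the untreated wild-type arrays cannot be told apart from a genotype effect, because after quantile normalization 60% of calls were higher, which met neither bound set beforehand, under 60% or at least 75%. A single sample as the source cannot be told apart either, because the lowest share without 1 untreated sample was 74.3%, without untreated wild type replicate 1, just under the bound of 75%. The count itself then fell from 613 to 113.

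Mitochondrial transcripts were higher after heat, with a median log2 difference of 3.32 in the wild type. A gain of all organelle transcripts is argued against, because the plastid genome had a median of 0.17. Transcripts of the nuclear copy on chromosome 2 cannot be told apart from those of the mitochondrion, because shared sequence can hybridise to the same probes. Probe sets listing a mitochondrial gene alone had a median of 3.17 (n = 24), those listing both 3.44 (n = 11) and those of the nuclear insertion alone 1.05 (n = 35). A biological rise of mitochondrial transcripts, or of the share of them that is primed for labelling, stays open and was not tested.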

How the results depend on the processing

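Quantile normalization between arrays and the adjustment of all lists together were tests chosen after the result was seen; the rest were planned. Unless the construction is named, the cause was not tested.

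Single genes were compared with 2952 alternative values: 2589 kept their direction and side of the threshold, 353 no longer passed, 9 came to pass and 1 reversed. That was LHCB4.1 with heat in the double mutant, 0.0118 (adjusted p = 0.907) with arrays centred on the reference genes. The naming rule picked these genes largely for big differences in the same data, so the share kept does not stand for all calls. Of all calls, that centring kept 5576 of 6027 and 5815 of 7725 for heat in the wild type and double mutant. It kept 259 of 613 and 174 of 204 between the untreated and heated genotypes, and 8 of 17 for the difference of responses.

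Centring on the reference genes gave 13087 probe sets for heat in the double mutant and 0 lists for the difference of responses. Keeping the upper 0.5 of probe sets by mean, which tested 11373 probe sets, gave 7 for the difference of responses and correlations of 0.936 for the heat responses and 0.498 for the genotype differences. The replicate block, with fewer degrees of freedom, gave 109 between the untreated genotypes, 102 after heat and 5 for the difference of responses. Array weights gave 683 after heat and 34 for the difference of responses. Quantile normalization gave 275 between the untreated genotypes, 253 of them shared with the 613, and 9 for the difference of responses. Fitting only the compared groups, with fewer samples, gave 109 and 33. A size of at least 1, a stricter demand by construction, gave 2228 and 2154 for heat in the wild type and double mutant, 159 and 88 for the genotypes before and after heat. Fry gave 7 lists for heat in the double mutant and 3 for the difference of responses, and the preset correlation 5 between the untreated genotypes and 3 for the difference of responses.

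Leaving out each sample in turn gave 3912 to 6528 probe sets for heat in the wild type, 6552 to 7624 in the double mutant, 113 to 862 between the untreated genotypes, 38 to 1061 after heat and 1 to 66 for the difference of responses. The lowest were without untreated wild type replicate 1 (3912 and 113), heated wild type replicate 1 (38) and untreated wild type replicate 2 (1), and 862, 1061 and 66 were without heated double mutant replicate 3. Lists numbered 5, 4, 2 to 4, 3 to 4 and 0 to 2. The correlations were 0.884 to 0.918 and 0.344 to 0.461. Without an untreated wild-type sample, the lone sample left was assumed to vary like the other groups.

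The alternatives for MSH1 and RECA3 were not run, since neither was named. The number of arrays limits the precision: in simulated data 80% of differences of 1 were recovered for heat in the wild type and 67% for the difference of responses. Those data gave 184 and 166 calls in all, with independent errors, against 6027 and 17 in the real data. The adjusted threshold follows the number of calls, so the real one was looser for heat and stricter for the difference of responses. The shares recovered therefore do not carry over directly.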

Other observations

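No test here was chosen after its result was seen. Other splits of the samples were counted for comparisons of groups of at least 3 samples. For heat in the double mutant 1 of 35 splits, the real one, gave as many probe sets (7725, against 400 in the highest other split) and as many lists (4, against 0). That share lies under 0.05, but 35 splits cannot exclude chance. Every other split mixes heated and untreated arrays within a group, so the heat difference widens its spread and few calls are likely. Between the heated genotypes the 10 splits are too few for a share under 0.05: the real split, 1 of 10, gave 204 probe sets and 3 lists, and the highest other 1 and 0.

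A hypothesis was that the untreated double mutant already shows part of the wild-type heat response. The covariance over probe sets of the untreated genotype difference with the wild-type heat difference was 0.0576 (r = 0.252), inside the interval of -0.00189 to 0.0710 from 100 simulations without a genotype effect, whose median was 0.0191. Such a shared response may exist but cannot be told apart from the error of the untreated wild type, which enters both differences.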
